A study of Arabidopsis thaliana with 8 samples.

How the data were processed

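RNA from 3-week-old Arabidopsis thaliana seedlings of Col-0 (3 samples) and of the bpm2,3,5 triple mutant (5 samples) was profiled on Agilent 1-colour gene expression arrays. Per the labels, the plants were grown on solid MS medium at 0.5 strength and 21 °C with 16 h of light and 8 h of dark. RNA came from about 100 mg of tissue and 500 ng of it was labelled with Cy3. All 8 arrays lay on 1 slide, in 2 columns, and were scanned in 1 scan.

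Each array came with its scanner text file, made by the authors with Feature Extraction 10.7.3.1. Per the file headers, its processed signal is a linear fluorescence intensity after subtraction of a spatial background surface and a multiplicative detrending, with low values replaced by a surrogate, and it is not normalized between arrays. The raw mean signal and the local background median in the same deposited files are linear intensity values too. The other deposited columns used, of unit other, are flags of 0 or 1 that mark spots well above background, saturated spots and outlier spots. The deposited series matrix holds log2 values, and the labels name limma for them without its version or steps. Its columns have nearly the same distribution, with medians from 6.963 to 6.968, and each correlated at r of 0.999 or more across spots with normexp (offset 50) and quantile normalization of the raw signals of its own array, more closely than with those of any other array.

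Each array held 61657 gene spots. Control spots were left out, as were 746 spots whose probe names several loci, and values of spots with an outlier flag were treated as missing, which affected 229 tested genes. The processed signal was taken as log2 and the log2 of the array's 75th percentile over the gene spots was subtracted. Spots of 1 probe were averaged. A probe entered the test if it was well above background on at least 3 of the 8 arrays (37364 of 59887 probes with 1 locus), and a gene was represented by its entering probe with the highest mean, which left 20988 of the 34408 genes on the array. The depth of an array was taken as its brightness and as its share of gene spots well above background, and the number of arrays limits the precision.

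The only comparison was bpm2,3,5 against Col-0, fitted with lmFit and eBayes of limma 3.58.1 without covariates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called and said to have risen or fallen. Where a gene was well above background on no array of a group, its fold is stated as a lower bound, with each value of that group raised to at least the lowest signal well above background on its array, and 16 called genes are of this kind. For 24 gene lists with 328 members, limma's camera with a preset correlation of 0.01 was run with Benjamini-Hochberg adjustment over the lists, and beside it camera with an estimated correlation and fry. No list passed with the estimated correlation (0 of 24), and 7 passed with fry, which tests whether the genes of a list move 1 way on balance. These were the lists of BPM and CUL3 genes, jasmonate biosynthesis, jasmonate repressors and catabolism, aliphatic glucosinolate, salicylic acid and immunity, the circadian clock and phosphate starvation. Missing values were filled with the group's mean for the list tests alone. Members were counted over all genes tested and adjusted over the list alone. Of the members 277 were matched by the symbol in the reference, 42 by the written locus that carries the symbol as a synonym or in its description, and 7 by the written locus alone. For KAT2 and CHI the reference gives the symbol to another gene, and the written locus was used, which departs from the matching rule as it was worded. Members that did not enter, 41 in all, among them FT, FMO1 and SAG12, are not described.

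The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 BPM and CUL3 genes, then the 12 largest rises and 12 largest falls among called genes whose Col-0 and bpm2,3,5 values do not overlap, and then up to 4 called members of each list with the smallest adjusted p, or the member with the largest change where none was called. A gene with a lower bound was ranked by its fitted change.

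The alternatives fixed then were normexp background correction with quantile or 75th percentile scaling, quantile normalization or median scaling of the processed signal, no filter on dim probes or a filter on all 8 arrays, and the mean of a gene's probes. They also took in eBayes with trend and robust, array weights, the slide column as a block, the replicate number as a block, the deposited values, and leaving out each array in turn. After the data were seen, fits without the 2 arrays least like their own groups, within each slide column, and with the log2 of the 75th percentile signal or the slide row as a covariate were added. Families of genes that share the stem of their symbol in the reference were tested for an excess of called genes with a 1-sided Fisher's exact test, adjusted over the families, and so were groups of genes that share a term in their description. All 56 splits of the 8 arrays into 3 and 5 were fitted in the same way.

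The procedure was tested on simulated data of the same size. Of 50 genes changed by each size, 16%, 68%, 86% and 92% were recovered at log2 changes of 1, 2, 3 and 4. Of 20770 unchanged genes 10 were called, 0 recovered genes had the wrong direction, and 0 genes were called when none was changed. The simulated genes were drawn independently, without any structure shared by the genes of an array such as its brightness or slide row. The simulation therefore does not measure the share of false calls in the real data. R 4.3.3 with the data.table package at version 1.17.8 and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 were used.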

Results

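Transcript levels were measured in 3-week-old Arabidopsis thaliana seedlings of the wild type Col-0 and of the triple mutant bpm2,3,5. By its name the mutant carries mutations in 3 of the BPM genes, which encode BTB/POZ-MATH proteins, the substrate adaptors of CUL3-based E3 ubiquitin ligases. There were 3 Col-0 and 5 bpm2,3,5 samples, each hybridised to its own 1-colour array, and all 8 arrays lay on 1 slide that was scanned once. Col-0 lay in slide rows 1, 2 and 1 and bpm2,3,5 in rows 3, 4, 2, 3 and 4, so only row 2 held both groups and an effect of the row is largely confounded with the genotype. The labels number the replicates but do not say whether they were separate sowings, so the p-values measure only the spread between samples. The arrays differed in brightness. The 75th percentile of the background-subtracted signal was 297, 1081 and 554 units on Col-0 replicates 1 to 3, and 866, 246, 1306, 268 and 198 units on bpm2,3,5 replicates 1 to 5. Between 48.5% (bpm2,3,5 replicate 5) and 71.4% (Col-0 replicate 3) of the gene spots were well above background, and 0 gene spots were saturated. The number of arrays limits the precision. Values below are log2 signals relative to the 75th percentile of the same array, given as mean ± SD, and log2 fold changes are bpm2,3,5 minus Col-0 with their SE. The array's annotation gives locus identifiers, whose digit before the G names the chromosome, and the order of genes along the chromosomes was taken from the reference.

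The comparison that the series names asks how expression in the triple mutant differs from that in Col-0. The 3 mutated genes gave far lower signals in bpm2,3,5. BPM2 (AT3G06190) fell by 5.18 on the log2 scale (SE 0.376), from 1.22 ± 0.0406 (n = 3) to −3.97 ± 0.699 (n = 5), with a limma adjusted p of 0.00329. BPM3 (AT2G39760) fell by 3.78 (SE 0.278), from 0.66 ± 0.391 to −3.12 ± 0.403, with the same adjusted p of 0.00329. BPM5 (AT5G21010) fell by 4.66 (SE 0.629, adjusted p = 0.0155), from −0.57 ± 0.0608 to −5.23 ± 1.22. The BPM5 probe was not well above background on any mutant array, so it is stated as at least 12.4-fold lower. BPM2 was well above background on 3 and BPM3 on 4 of the 5 mutant arrays. The other probe of each gene gave log2 fold changes of −5.62 for BPM2, −2.46 for BPM3 and −4.31 for BPM5. The remaining genes of the family did not pass the test. BPM1 (AT5G19000) had a log2 fold change of −0.33 (SE 0.176, adjusted p = 0.351) and BPM6 (AT3G43700) of −0.45 (SE 0.179, adjusted p = 0.233). BPM4 (AT3G03740) had −0.07 (SE 0.155, adjusted p = 0.824), and this value was 0.16 when arrays were scaled by their median. CUL3A (AT1G26830) and CUL3B (AT1G69670), the cullins of the complex, had −0.47 (SE 0.439, adjusted p = 0.579) and −0.52 (SE 0.344, adjusted p = 0.447), and 0.30 and 0.028 with the slide row as a covariate. CUL3A read −0.03 on bpm2,3,5 replicate 5 and 1.49 to 2.02 on the other mutant arrays. Other probes gave −0.40 and −1.13 for BPM6, −0.45 for CUL3A and −1.07 for CUL3B. None of them passed (limma adjusted p over probes from 0.193 to 0.611). BPM6 nevertheless lay lower on every mutant array than on every Col-0 array. The list of the 8 BPM and CUL3 genes, which holds the 3 mutated genes themselves, passed (0 rose and 3 fell, and the same counts when adjusted over the list alone; camera adjusted p = 3.02e-05, and adjusted p = 0.0926 with an estimated correlation). With a filter on all 8 arrays, which takes out the mutated genes, the list did not pass (adjusted p = 0.115). The labels do not place the mutations within the genes, so whether the probes lie before or beyond them is not known. The BPM5 call was lost with normexp background correction and the 75th percentile (−2.28, adjusted p = 0.0607), without Col-0 replicate 1 (adjusted p = 0.0584) and without Col-0 replicate 3 (adjusted p = 0.0697), and bpm2,3,5 replicate 5 read −3.08 where the other mutant arrays read −6.07 to −5.61, all of them values not well above background.

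**Figure D1:**
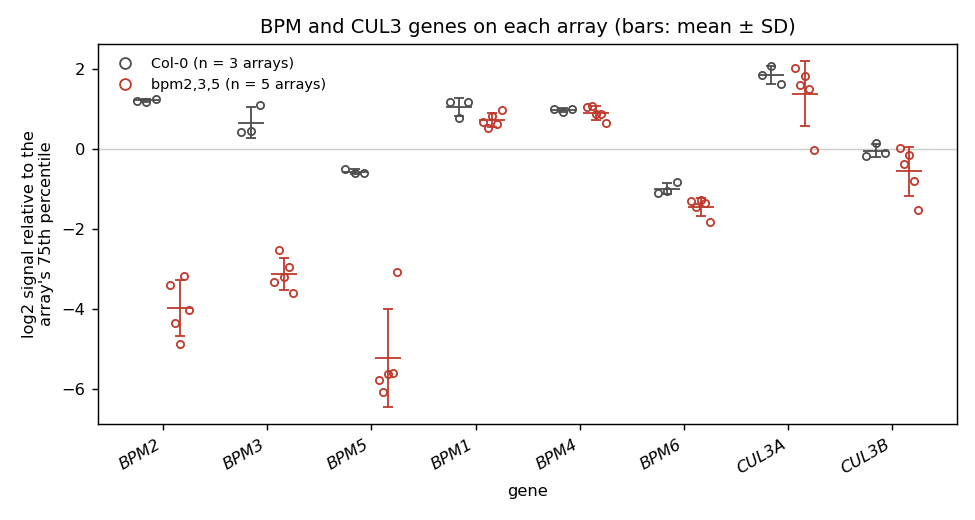
Log2 signal relative to the array's 75th percentile (y axis) of the BPM and CUL3 genes (x axis) on each of the 3 Col-0 and 5 bpm2,3,5 arrays, with bars for mean ± SD. BPM2, BPM3, BPM5 and BPM6 lie lower on every mutant array than on every Col-0 array, though BPM6 was not called. Apart from BPM2, BPM3 and BPM5, the log2 fold changes of the probes shown lie between −0.52 and −0.07. That of BPM4 was 0.16 with median scaling. Those of CUL3A and CUL3B were 0.30 and 0.028 with the slide row as a covariate.

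The genes with the largest rises in the mutant included PHI-1, EXO, TCH4 and JAZ7. PHI-1 (AT1G35140) and EXO (AT4G08950), related genes of the EXORDIUM family, rose by 5.94 (SE 0.951, adjusted p = 0.0243) and 5.80 (SE 0.452, adjusted p = 0.00377). TCH4 (AT5G57560), a touch-inducible xyloglucan endotransglucosylase, rose by 5.32 (SE 0.514, adjusted p = 0.00805), from −1.66 ± 0.462 (n = 3) to 3.66 ± 0.930 (n = 5). The related XTR6 (AT4G25810) rose at least 10.3-fold (adjusted p = 0.0313), since it was well above background on 0 of the Col-0 arrays. JAZ7 (AT2G34600), a repressor of jasmonate signalling, rose by 5.00 (SE 0.604, adjusted p = 0.0110). AOC3 (AT3G25780), an allene oxide cyclase of jasmonate synthesis, rose by 3.83 (SE 0.545, adjusted p = 0.0179), and the glutaredoxin gene GRX480 (AT1G28480) by 3.98 (SE 0.587, adjusted p = 0.0184). The mitochondrial carrier gene DIC2 (AT4G24570) rose by 4.01 (SE 0.674, adjusted p = 0.0281), and BAP1 (AT3G61190), which encodes a C2 domain protein, by 3.43 (SE 0.700, adjusted p = 0.0470). The ERF/AP2 transcription factor gene AT1G33760 rose at least 15.5-fold (adjusted p = 0.0330), AT1G20310, of unknown function, at least 6.39-fold (adjusted p = 0.0178), and AT5G28237, a pyridoxal phosphate enzyme gene, at least 9.70-fold (adjusted p = 0.0161). The other probe of AT1G20310 gave 0.77 (adjusted p = 0.671), far from that rise, and the other probes of PHI-1 (4.64), AT1G33760 (4.75), GRX480 (2.43) and BAP1 (3.17) did not pass on their own. The lower bounds hold only for the background-subtracted signal. In the deposited values, which resemble normexp with an offset of 50, AT1G33760 was 4.57-fold higher and not called (adjusted p = 0.0858), XTR6 3.5-fold, AT1G20310 2.65-fold and AT5G28237 2.62-fold, and BAP1 was not called either (1.71, adjusted p = 0.0652). With normexp and the 75th percentile none of these 5 genes was called (adjusted p from 0.0733 for AT5G28237 to 0.292 for AT1G20310). With the slide column as a block the calls of PHI-1 (5.83), AT1G33760 (5.70), XTR6 (4.14), DIC2 (4.07) and BAP1 (3.65) were lost (adjusted p from 0.0565 to 0.0700) although the fitted changes were about as large. Leaving out 1 array in turn ended the call of BAP1 in 8 of 8 cases, of XTR6 and AT1G33760 in 6, of DIC2 in 5, of PHI-1 in 4, of AT1G20310 and GRX480 in 3 and of AT5G28237 in 1. On bpm2,3,5 replicate 5, GRX480 read 3.46, against 1.90 to 2.27 on the other mutant arrays.

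**Figure D2:**
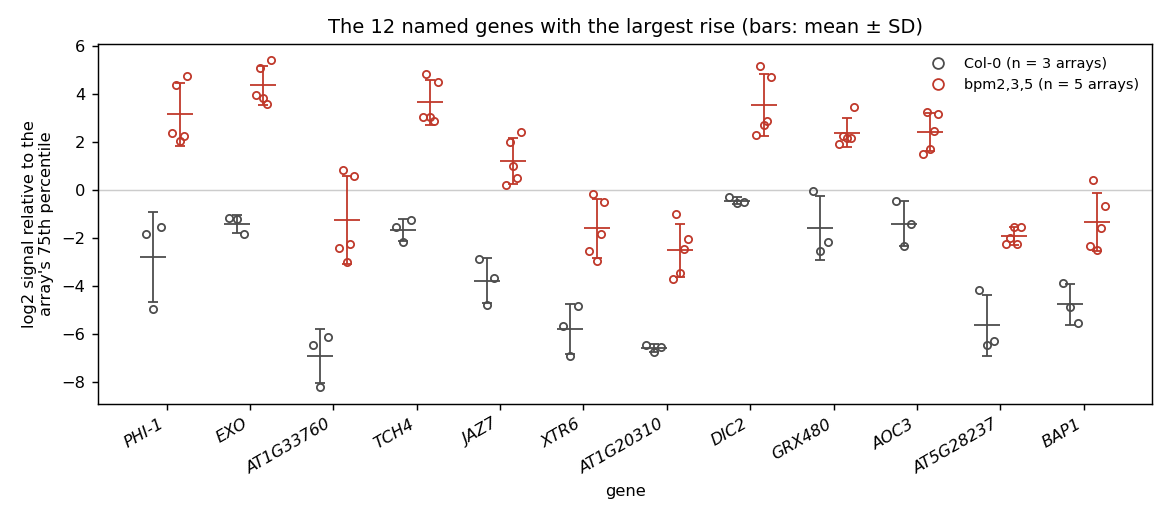
Log2 signal relative to the array's 75th percentile (y axis) of the 12 called genes with the largest fitted rise (x axis) on each of the 3 Col-0 and 5 bpm2,3,5 arrays, with bars for mean ± SD. The genes were chosen among those whose groups do not overlap, and the rises run from 3.43 for BAP1 to 5.94 for PHI-1.

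Besides the BPM genes, those with the largest falls included FLC, NIG1, BBX16 and GOLS3. FLC (AT5G10140), a MADS-box repressor of flowering, fell at least 6.14-fold (adjusted p = 0.0130), from −1.59 ± 1.08 (n = 3) to a level not well above background on any mutant array. NIG1 (AT5G46830), a calcium-binding transcription factor of salt stress, fell by 3.25 (SE 0.429, adjusted p = 0.0144). CIPK25 (AT5G25110), a kinase of the calcineurin B-like calcium sensors, fell by 2.69 (SE 0.481, adjusted p = 0.0330). It was well above background on only 1 of the 5 mutant arrays, so the size of this fall rests mostly on undetected values. BBX16 (AT1G73870), a B-box zinc finger gene, fell by 2.74 (SE 0.302, adjusted p = 0.00932). BBX16 read −2.07 on bpm2,3,5 replicate 2 and −3.33 to −3.05 on the other mutant arrays. GOLS3 (AT1G09350), a galactinol synthase, fell by 2.68 (SE 0.376, adjusted p = 0.0177), from 1.24 ± 0.477 (n = 3) to −1.45 ± 0.612 (n = 5). AT5G62280 and AT2G21980, of unknown function, fell by 3.05 (SE 0.472, adjusted p = 0.0221) and by 3.65 (SE 0.386, adjusted p = 0.00932). AT2G21980 and NIG1 were each well above background on 2 of the 5 mutant arrays, so the size of their fitted falls rests in part on undetected values. The protein kinase gene AT5G26150 fell at least 2.98-fold (adjusted p = 0.0346), and AT3G19323, a pseudogene of a poly(A) binding protein, at least 2.73-fold (adjusted p = 0.0305). On each mutant array AT5G26150 and AT3G19323 read the same value, from −7.93 to −5.22, a floor of the array and not a level of the gene. FLC, AT2G21980, NIG1 and CIPK25 also read −6.07 on bpm2,3,5 replicate 2. The SE and adjusted p of such falls therefore do not fully measure the spread of the gene in the mutant. With normexp and the 75th percentile the calls of FLC (−1.64, adjusted p = 0.212), AT2G21980 (−1.21, adjusted p = 0.308), NIG1 (−1.53, adjusted p = 0.213), CIPK25 (−0.76, adjusted p = 0.522), AT5G26150 (−1.05, adjusted p = 0.498) and AT3G19323 (−0.86, adjusted p = 0.548) were lost. In the deposited values FLC was 3.46-fold lower (adjusted p = 0.00525), AT5G26150 1.93-fold and AT3G19323 1.63-fold, all below their bounds on the background-subtracted signal, and the other probe of BBX16 gave −1.53 (adjusted p = 0.127). With the slide column as a block the calls of AT5G26150, AT3G19323 and CIPK25 were lost (adjusted p = 0.0659, 0.0538 and 0.0565), with fitted changes of −4.01, −3.94 and −2.81. Leaving out 1 array in turn ended the calls of AT5G26150 and CIPK25 in 7 of 8 cases, of AT3G19323 and AT5G62280 in 6, of GOLS3 in 2 and of NIG1 and BBX16 in 1.

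In all, 289 genes were higher and 224 lower in bpm2,3,5, out of 20988 genes tested (limma, adjusted p under 0.05), and 258 and 171 of them by 2-fold or more. The 2 groups did not overlap in any of these 513 genes, which the call itself makes likely, nor in 18.3% of all genes tested. Chance gives 3.57% for a single gene, but genes on the same arrays vary together, so this share is not a test. Of the called genes 285 higher and 215 lower ones were protein coding. The microRNA genes gave 0 higher and 3 lower of 70 tested, miR3932a (−2.30), miR3932b (−1.95) and MIR863 (−1.27), named after their values were seen. With median scaling 279 genes were higher and 61 lower, so the balance of the directions depends on the scaling. With the array's column on the slide as a block 91 genes were higher and 96 lower, the folds of the called genes being 1.01 times and the SEs of all genes 1.07 times as large in the median, and without Col-0 replicate 3 and bpm2,3,5 replicate 5, the arrays least like their own groups, 145 were higher and 115 lower. With the slide row as a covariate 0 genes were higher and 0 lower. All 513 kept their sign, but 1041 of the 20988 genes then had an unadjusted p under 0.05, about the 1 in 20 that chance gives, against 3857 without the covariate. The folds of the called genes were then 0.843 times as large in the median, and the SEs of all genes 1.70 times, since the row nearly parts the groups. The mutated genes, named in advance, kept their folds, with −5.42 (SE 0.671) for BPM2, −3.77 (SE 0.501) for BPM3 and −5.56 (SE 1.06) for BPM5, which argues against a linear trend along the rows as the whole cause there, while for the other genes the row was not excluded. Without Col-0 replicate 1 there were 67 genes higher and 40 lower. The count of called genes was 214 and 36 without Col-0 replicates 2 and 3 in turn, and 145, 127, 153, 202 and 762 without bpm2,3,5 replicates 1 to 5. Of the 43 called genes named by rule, BPM2, BPM3, EXO, TCH4, FLC and AT2G21980 kept their call whichever single array was left out, though FLC and AT2G21980 lost it with normexp and the 75th percentile, whereas BAP1 and CCA1 lost it in all 8 cases. Without a filter on dim probes 3 of the 43 kept their call, and 0 with the replicate number as a block or with the slide row as a covariate.

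Genes of jasmonate synthesis and of its repressors and catabolism lay higher in the mutant by camera and by fry. Jasmonate is the wound hormone whose perception releases MYC transcription factors from JAZ repressors. Among 18 genes of jasmonate repressors and catabolism 7 rose and 0 fell, and 13 rose and 1 fell when adjusted over the list alone. JAZ7, JAZ9 (AT1G70700, 1.98, SE 0.321, adjusted p = 0.0247), JAZ10 (AT5G13220, 2.36, SE 0.383, adjusted p = 0.0249) and JAZ6 (AT1G72450, 1.0, SE 0.146, adjusted p = 0.0182) rose. So did CYP94C1 (2.84), which oxidises the active hormone, and the amidohydrolase genes ILL6 (2.06) and IAR3 (1.2), named after their values were seen. The median log2 fold change of this list was 1.25 (camera adjusted p = 1.07e-08, and adjusted p = 0.194 with an estimated correlation). Of 14 biosynthesis genes AOC3 and OPR3 (AT2G06050, 1.57, SE 0.307, adjusted p = 0.0417) rose, 0 fell, and 8 rose when adjusted over the list alone. The median of the biosynthesis list was 0.91 (camera adjusted p = 1.42e-05, and adjusted p = 0.319 with an estimated correlation). Of 12 wound-response genes of the MYC branch 0 rose or fell, and 1 rose when adjusted over the list alone, with a median of 1.31 (camera adjusted p = 0.000119, adjusted p = 0.384 with an estimated correlation, and adjusted p = 0.130 with fry). TAT3 (AT2G24850) had the largest value there, 2.43 (SE 0.863, adjusted p = 0.193). Of 8 genes of the jasmonate and ethylene ERF branch 0 rose and 1 fell, with the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.901). The member that fell was CHI-B (AT3G12500), a basic chitinase, by 1.11 (SE 0.218, adjusted p = 0.0426), but its value was −0.13 in the deposited values (adjusted p = 0.676) and −0.0071 with normexp and the 75th percentile (adjusted p = 0.998). Per array, the mean of the repressor and catabolism genes, centred on each gene's mean, was −0.69, −1.48 and −0.74 in Col-0 and 0.11, 0.92, 0.31, 0.50 and 1.08 in bpm2,3,5 replicates 1 to 5. Those of the MYC branch overlapped between the groups, at 0.65, −1.93 and −1.23 in Col-0 and 0.76, 0.24, 0.62, 0.50 and 0.40 in bpm2,3,5. The lowest mutant means of the repressor and catabolism genes were those of the brightest mutant arrays, replicates 1 and 3. The other probe of JAZ10 gave 0.79 (adjusted p = 0.414), as did the gene with a filter on all 8 arrays (adjusted p = 0.370), and JAZ6 and OPR3 lost their calls with median scaling (adjusted p = 0.0892 and 0.0623). JAZ9 read 5.40 on bpm2,3,5 replicate 5 and 4.16 to 4.49 on the other mutant arrays. With the slide column as a block OPR3 (1.61), JAZ9 (1.93) and CHI-B (−1.19) lost their calls (adjusted p = 0.0775, 0.0577 and 0.0547) with changes about as large. Without a filter on dim probes AOC3 and JAZ7 lost theirs (adjusted p = 0.0821 and 0.0621), and so they did without Col-0 replicate 3 (adjusted p = 0.0779 and 0.0583), while the other jasmonate genes named by rule lost theirs without 6 or 7 of the 8 arrays in turn.

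**Figure D3:**
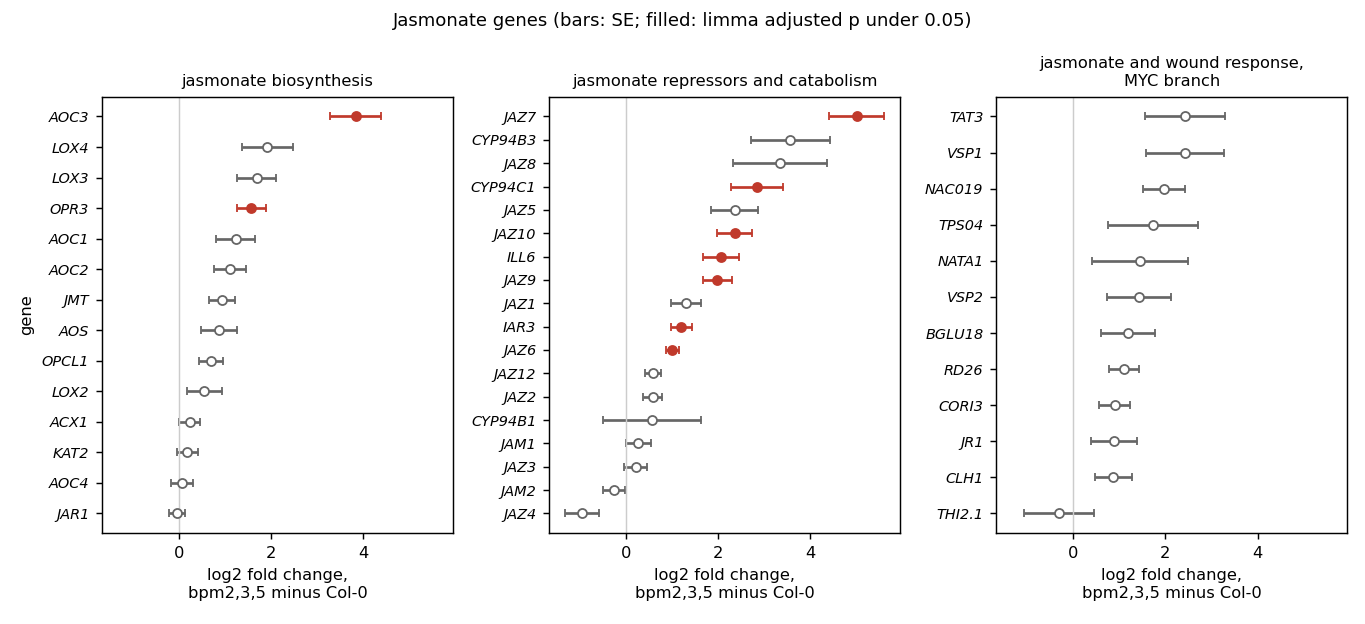
Log2 fold change, bpm2,3,5 minus Col-0 (x axis), with SE bars, for the tested genes (y axis) of the 3 lists of jasmonate biosynthesis, of repressors and catabolism, and of the MYC branch of the wound response. Filled points passed limma's adjusted p of 0.05 (2, 7 and 0 genes), and the list medians were 0.91, 1.25 and 1.31.

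Genes of salicylic acid and immunity lay higher, and those of aliphatic glucosinolate and of flavonoid synthesis lower, in the mutant by camera. Of 16 genes of salicylic acid and immunity 2 rose and 0 fell (4 rose and 0 fell when adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.000119, and adjusted p = 0.319 with an estimated correlation). The risers were GRX480 and SARD1 (AT1G73805), a regulator of salicylic acid synthesis, which rose by 1.36 (SE 0.148, adjusted p = 0.00932). Of 15 genes of aliphatic glucosinolate synthesis, which makes methionine-derived defence compounds, 0 rose and MAM3 (AT5G23020) fell, by 2.57 (SE 0.458, adjusted p = 0.0327). Adjusted over the list alone 0 rose and 4 fell, and the median was −0.46 (camera adjusted p = 0.00196, and adjusted p = 0.319 with an estimated correlation). Of 14 flavonoid and anthocyanin genes 0 rose and MYBL2 (AT1G71030), a repressor of anthocyanin synthesis, fell by 1.61 (SE 0.309, adjusted p = 0.0400). Adjusted over the list alone 1 rose and 3 fell, and the median was −0.97 (camera adjusted p = 0.0135, and adjusted p = 0.447 with an estimated correlation). Of 10 heat shock genes HSFA3 (AT5G03720), a heat stress transcription factor, rose by 1.32 (SE 0.252, adjusted p = 0.0398), 0 fell, and 2 rose and 0 fell when adjusted over the list alone. The heat shock median was 0.62 (camera adjusted p = 0.0461, and adjusted p = 0.447 with an estimated correlation). The flavonoid list did not pass without Col-0 replicate 2 (adjusted p = 0.188), nor did the heat shock list without Col-0 replicate 1 or 2 or bpm2,3,5 replicate 2, 3 or 4 (highest adjusted p = 0.165), nor with the slide column as a block (adjusted p = 0.0613). The flavonoid and heat shock lists did not pass with fry either (adjusted p = 0.135 and 0.157), HSFA3 was not called in the deposited values (0.82, adjusted p = 0.0573), and MYBL2 was not called with median scaling (adjusted p = 0.098). With the slide column as a block MAM3 (−2.63), HSFA3 (1.28) and MYBL2 (−1.63) were not called (adjusted p = 0.0656, 0.0834 and 0.0792), though their changes were about as large, and leaving out 1 array in turn ended their calls in 6, 7 and 7 of 8 cases. With the slide row as a covariate the aliphatic glucosinolate list did not pass (adjusted p = 0.0798). The per-array means of 2 of these lists overlapped between the groups. That of salicylic acid and immunity was −0.02 on Col-0 replicate 1 and −0.05 and −0.10 on bpm2,3,5 replicates 2 and 5, and that of heat shock was 0.10 on Col-0 replicate 3 and −0.06 to 0.63 in bpm2,3,5.

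Several other lists held called members without passing camera's test. Of 19 flowering time genes 0 rose and 3 fell, and 3 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.405). Besides FLC these were SPL9 (AT2G42200), which promotes the adult phase, by 0.91 (SE 0.170, adjusted p = 0.0370), and TOE1 (AT2G28550), a repressor of flowering, by 0.96 (SE 0.180, adjusted p = 0.0375). SPL9 read −1.34 on bpm2,3,5 replicate 2 and −0.92 to −0.77 on the other mutant arrays. Of 13 circadian clock genes 0 rose and 2 fell, and 3 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.139, fry adjusted p = 0.0343). CCA1 (AT2G46830), a morning repressor of the clock, fell by 1.90 (SE 0.359, adjusted p = 0.0384) and LNK1 (AT5G64170) by 1.2 (SE 0.225, adjusted p = 0.0376). LNK1 read −1.38 on bpm2,3,5 replicate 5 and −0.75 to −0.51 on the other mutant arrays. Of 9 cold and CBF genes 0 rose, and GOLS3 and CBF3 (AT4G25480), a cold-response activator, fell, CBF3 by 1.66 (SE 0.241, adjusted p = 0.0182), while 2 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.811). Of 12 genes of senescence and dark response 2 rose and 0 fell, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.595). They were SEN4 (AT4G30270), a xyloglucan endotransglucosylase gene, by 2.24 (SE 0.373, adjusted p = 0.0275), and WRKY53 (AT4G23810), a transcription factor of leaf senescence, by 2.16 (SE 0.370, adjusted p = 0.0292). Of 21 abscisic acid response genes 1 rose and 0 fell, and 2 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.288). It was CYP707A1 (AT4G19230), which breaks the hormone down, by 2.33 (SE 0.450, adjusted p = 0.0407). Of 5 phosphate starvation genes 0 rose and SPX1 (AT5G20150), a phosphate sensor, fell by 1.26 (SE 0.163, adjusted p = 0.0131), and 0 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0798, fry adjusted p = 0.00994). SPX1 lies among the 100 tested genes on either side of the mutated BPM5, and whether its fall comes from linkage to that locus was not tested. Of 14 fatty acid synthesis genes 1 rose and 0 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.405). It was SUS2 (AT5G49190), a sucrose synthase rather than an enzyme of fatty acid synthesis, by 1.35 (SE 0.206, adjusted p = 0.0211). CCA1 was not called in the deposited values (−0.46, adjusted p = 0.202), nor were CYP707A1 (0.94, adjusted p = 0.0609) and SUS2 (0.70, adjusted p = 0.0592) with normexp and quantile normalization. SPL9, TOE1, LNK1, CCA1 and SPX1 were not called with median scaling (adjusted p from 0.0869 to 0.443), nor were TOE1 and WRKY53 with the mean of probes (adjusted p = 0.0616 and 0.0577). With the slide column as a block SPL9 (−0.95), LNK1 (−1.18), CCA1 (−1.96), CYP707A1 (2.39), SEN4 (2.16) and WRKY53 (2.27) were not called (adjusted p from 0.0513 to 0.0792), with changes about as large. Leaving out 1 array in turn ended the calls of SPL9, TOE1, LNK1 and CYP707A1 in 7 of 8 cases, of WRKY53 and SUS2 in 6, of SEN4 in 5 and of CBF3 in 3. Apart from that of FLC, each of these calls was lost without at least 1 array, that of SPX1 only without Col-0 replicate 3 (adjusted p = 0.0675), and the clock call of CCA1 without any of the 8.

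The remaining lists had 0 called members. The 13 tested genes whose proteins are named in the literature as bound or degraded by BPMs did not pass (camera adjusted p = 0.539), and 2 rose and 1 fell when adjusted over the list alone. MYC2 (AT1G32640), the jasmonate transcription factor among them, had a log2 fold change of 1.09 (SE 0.317, adjusted p = 0.126). The 14 indolic glucosinolate genes did not pass (camera adjusted p = 0.105) and 0 changed when adjusted over the list alone, with the largest value in CYP81F4 (AT4G37410), 2.77 (SE 0.816, adjusted p = 0.131). Of 9 auxin response genes 0 rose and 3 fell when adjusted over the list alone, with the largest value in IAA29 (AT4G32280), −2.22 (SE 0.549, adjusted p = 0.0869). The median of the auxin list was 0.24 while its mean was −0.38 and camera pointed down (adjusted p = 0.539). Of 8 iron deficiency genes 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.673), with the largest value in FRO2 (AT1G01580), a ferric chelate reductase, −1.57 (SE 0.352, adjusted p = 0.0636). FRO2 and IAA29 were each called in 3 of 24 alternatives (lowest limma adjusted p = 0.0200 and 0.0403). Adjusted over the list alone 0 of 17 photosynthesis genes changed (camera adjusted p = 0.594), and LHCB3 (AT5G54270), a light-harvesting protein gene, had −0.43 (SE 0.563, adjusted p = 0.696). Likewise 0 of 8 cell cycle genes changed (camera adjusted p = 0.405), with the largest value in CDKB1;1 (AT3G54180), 0.62 (SE 0.299, adjusted p = 0.308). Among markers of other tissues, 0 of 8 root genes and 0 of 2 flower and seed genes changed when adjusted over the list alone (camera adjusted p = 0.450 for both). COBL9 (AT5G49270), a gene of root hairs, had −2.03 (SE 1.09, adjusted p = 0.357), a value carried by Col-0 replicate 3, which read −0.63 where the other Col-0 arrays read −4.52 and −4.74, and CRA1 (AT5G44120), a seed storage protein gene, −1.03 (SE 0.667, adjusted p = 0.435). The flower and seed mean was highest on the same array, 2.14, against 0.51 or less on the others. A p above the threshold in these lists does not show that their genes were alike in both groups.

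**Figure D4:**
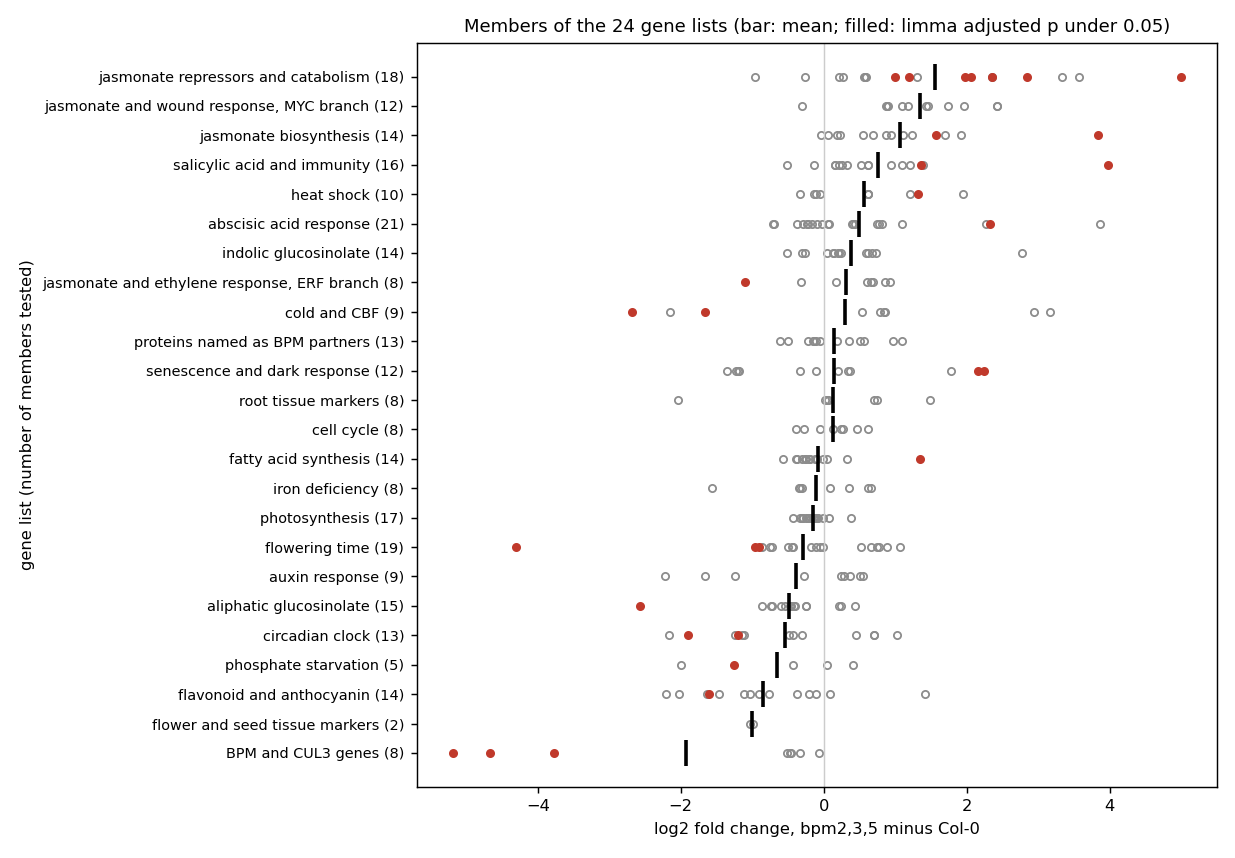
Log2 fold change, bpm2,3,5 minus Col-0 (x axis), of each tested member (points) of the 24 gene lists (y axis, with the number of members tested), with a bar at each list's mean. Filled points passed limma's adjusted p of 0.05, and the jasmonate repressor and catabolism list has the highest mean, 1.56, while the BPM and CUL3 list has the lowest, −1.93.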

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

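No test in this part was chosen after the result was seen. In 57 genes, 24 list means and 5 array measures, 86 in all, the highest or lowest of the 5 bpm2,3,5 samples was set against the others, and its gap to the nearest, as a share of the whole range, was compared with a limit of 0.71 that chance passes in about 1 of 20 groups. It was passed 8 times, and 5 of these came from bpm2,3,5 replicate 5, the dimmest array. BPM5, a mutated gene, read −3.08 on replicate 5 and −6.07 to −5.61 on the others (share 0.847), but its probe was well above background on 0 of the 5 arrays, so this is a gap between undetected values on arrays of unequal brightness and says nothing of the gene. CUL3A, a cullin, read −0.03 there and 1.49 to 2.02 on the others (share 0.741). GRX480, a glutaredoxin gene that rose, read 3.46 there and 1.90 to 2.27 on the others (share 0.767). JAZ9, a jasmonate repressor gene, read 5.40 there and 4.16 to 4.49 on the others (share 0.739). LNK1, a clock gene, read −1.38 there and −0.75 to −0.51 on the others (share 0.724). On bpm2,3,5 replicate 2 the B-box gene BBX16 read −2.07, against −3.33 to −3.05 (share 0.781), and SPL9 read −1.34, against −0.92 to −0.77 (share 0.739). The SD of the processed signal of the negative control spots was 732 on bpm2,3,5 replicate 3 and 7.44 to 66.3 on the others (share 0.919). Chance alone would give about 1 in 20 of these, and no biological explanation was tested.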

How the results depend on the processing

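The fits without 2 arrays, within each slide column and with brightness or the slide row as a covariate were chosen only after the result was seen. BPM2 and BPM3 stayed lower under each of 24 alternatives and passed in 20, but not with the slide row as a covariate (−5.42 and −3.77, adjusted p = 0.462 for both), the replicate number as a block (−5.43 and −3.67, 0.232 for both) or within slide column 1 (0.242) or 2 (0.200). Without 1 array in turn the lists of jasmonate biosynthesis, jasmonate repressors and catabolism, the MYC branch, BPM and CUL3 genes, salicylic acid and aliphatic glucosinolate passed in 8 of 8 cases, the flavonoid list in 7 and the heat shock list in 3. With a filter on all 8 arrays, which takes out the 3 mutated genes, the BPM list did not pass (adjusted p = 0.115). Of the 513 called genes 0 changed sign in any alternative that tested them. For the fits that left out arrays or used 1 slide column this was fixed in advance, since the groups did not overlap in these genes. The 43 called genes named by rule kept 36 calls with normexp and quantile, 26 with normexp and the 75th percentile, 33 with median scaling, 3 without a filter, 42 with array weights, 23 with the slide column as a block, 38 with the deposited values, 16 without the 2 arrays least like their groups, 43 with brightness as a covariate and 0 with the slide row as a covariate. Genes counted as higher or lower were affected more. Normexp and quantile gave 470 higher genes, the deposited values 504, trend and robust 437 and a filter on all 8 arrays 445. Array weights gave 674 higher and 662 lower, 396 of the former by 2-fold or more. Normexp and the 75th percentile gave 181 higher and 137 lower (145 and 79 by 2-fold or more). Median scaling gave 61 lower, 61 of them by 2-fold or more, with the median log2 fold change of all genes at 0.18 rather than −0.05. Without a filter 34408 genes were tested and 3 were higher and 2 lower (3 and 2 by 2-fold or more), with 3092 at an unadjusted p under 0.05. The slide column as a block gave 91 higher and 96 lower (90 and 95 by 2-fold or more), and the fit without the 2 arrays 145 and 115 (131 and 90). limma called 0 genes higher and 0 lower, of any size, with the replicate block, in column 1, in column 2 and with the slide row as a covariate, where 3045, 2675, 2272 and 1041 genes had an unadjusted p under 0.05. The columns hold fewer arrays, and column 2 has 1 Col-0 array, taken to vary like the mutant arrays, so its values decide nothing. The rows nearly part the groups. In the replicate block, bpm2,3,5 replicates 4 and 5 each form a block of their own and add nothing to the comparison. It thus rests on the pairs of replicates 1 to 3, with few arrays left to measure the spread. The folds of the called genes were then 0.978 times and the SEs of all genes 0.902 times as large in the median. The loss of all calls there does not show a smaller difference. Samples of the same replicate number correlated at −0.18, −0.12 and −0.22 across genes after centring, and those of different numbers at −0.33 to 0.41. This gives no sign that the numbers pair the samples, but so few correlations do not exclude a pairing. Without 1 array in turn 18 to 359 genes were higher and 18 to 403 lower (18 to 252 and 18 to 212 by 2-fold or more), lowest without Col-0 replicate 3 and highest without bpm2,3,5 replicate 5. Of 24 lists 8 passed, with 5 in column 2 and 0 with an estimated correlation.

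Uncalled values reversed, most of them near 0. With the slide row as a covariate CUL3A was 0.30, CUL3B 0.028, the cold mean −0.28 and the iron deficiency mean 0.42, and the ERF branch, photosynthesis and fatty acid lists passed (adjusted p = 0.0423, 0.000158 and 0.0467). The BPM4 log2 fold change was 0.16 with median scaling, 0.024 with the replicate block, 0.0015 without the 2 arrays and 0.096 in column 1. The mean of the iron deficiency list was 0.066 with normexp and quantile, 0.091 with normexp and the 75th percentile, 0.13 with median scaling, 0.18 with a filter on all 8 arrays and in column 2, 0.00012 with array weights and 0.063 with the deposited values. With median scaling the photosynthesis mean was 0.086 and the fatty acid mean 0.16, the latter 0.041 with the mean of probes. The root mean was −0.0087 without a filter and −0.0039 with the mean of probes. The senescence mean was −0.087 without a filter and −0.094 in column 2, the cold mean −0.0090 with array weights, the cell cycle mean −0.19 in column 2, and the ERF branch mean −0.026 without the 2 arrays and −0.21 in column 1. Without 1 array in turn the list means ran from −0.30 to 1.05 for the ERF branch, −0.020 to 0.31 for root, −0.46 to 0.093 for photosynthesis, −0.060 to 0.26 for senescence, −0.18 to 0.042 for iron deficiency and −0.039 to 0.24 for the cell cycle. The cause of these differences was not tested, apart from the fewer arrays in the columns and the larger number of genes without a filter. Signal over background limits what can be read from genes that were dim in either group.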

Other observations

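In this part, the tests of symbol families, touch genes and clock genes, the tests of slide column and row, and the fit with brightness as a covariate, were chosen only after the result was seen. The SAUR genes, small auxin-induced genes many of which act in cell elongation, were the gene family with the strongest excess of falls. Of 16 tested SAUR genes 0 rose and 9 fell, among them SAUR20 (−1.97, SE 0.261, limma adjusted p = 0.0144), SAUR23 (−1.77, SE 0.276, adjusted p = 0.0223) and SAUR15 (−1.75, SE 0.248, adjusted p = 0.0179), and the family had an adjusted p of 5.73e-11 by Fisher's exact test over 194 symbol families, while 0 of 112 groups sharing a term in their description passed in either direction. Of 18 CIPK kinase genes 0 rose and 5 fell (adjusted p = 0.000492 by the exact test), including CIPK20 (−2.20, SE 0.325), CIPK17 (−1.51, SE 0.279) and CIPK7 (−1.10, SE 0.152). Of 15 B-box genes 0 rose and 4 fell (adjusted p = 0.00371 by the exact test), which were BBX16, BBX30 (−1.87, SE 0.294), BBX28 (−1.35, SE 0.194) and BBX18 (−1.26, SE 0.176). Several SAUR genes are near-identical paralogs whose probes can read each other's transcripts, which was not tested. Of those that fell, SAUR20, SAUR22, SAUR23 and SAUR24 lie close together (AT5G18020 to AT5G18080), as do SAUR27, SAUR28 and SAUR29 (AT3G03820 to AT3G03840). The exact test counts genes as independent, so the p-values of all families can overstate the evidence where members vary together.

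Genes with the symbol XTH, for xyloglucan endotransglucosylases that remodel the cell wall, were over-represented among the rises. Of 21 genes with this symbol in the reference, where TCH4 and XTR6 do not carry it, 5 rose (adjusted p = 0.00262 by the exact test), including XTH9 (3.19, SE 0.382), XTH25 (3.15, SE 0.479) and XTH18 (3.34, SE 0.652), while XTH31 fell by 0.98 (SE 0.180). Of 50 WRKY transcription factor genes 6 rose (adjusted p = 0.0106 by the exact test), including WRKY18 (2.85, SE 0.329) and WRKY11 (1.73, SE 0.214), while WRKY65 fell at least 2.06-fold. Of 10 genes with a JAZ symbol 3 rose and 0 fell (adjusted p = 0.0257 by the exact test). Under each of the scalings tried, the family median kept its sign in all 6 families, from −1.21 to −0.98 for SAUR and from 0.55 to 1.0 for XTH. The number of genes that fell ranged from 2 to 10 for SAUR, 2 to 5 for CIPK and 2 to 4 for the B-box genes. The number that rose ranged from 3 to 6 for XTH, 4 to 8 for WRKY and 2 to 4 for JAZ. These genes were named after their values were seen.

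Jasmonate and touch genes lay higher in the mutant by camera, though the 3 jasmonate lists did not pass with an estimated correlation (adjusted p = 0.194, 0.319 and 0.384), and of 15 genes known to respond to touch, of which ZAT10 and ZAT12 are in the cold list too and 0 in the jasmonate lists, 14 were tested, all with positive log2 fold changes, and TCH2, TCH4, ERF104 and MYB44 rose. Unequal brightness of the arrays is argued against as the whole cause of the jasmonate part, since the mean of the repressor and catabolism list was 1.43 with brightness as a covariate and 1.56 without, and 9 of its 18 members then rose. So is the slide column, with a mean of 1.50 with the column as a block (95% interval of the per-array means 0.64 to 2.37), though 3 members rather than 7 then rose. The slide row cannot be told apart from the genotype, since the rows nearly part the groups and the mean with the row as a covariate was 1.23 with an interval from −0.16 to 2.62. The touch genes had a mean log2 fold change of 2.71 (camera p = 5.33e-14, and p = 0.0248 with an estimated correlation), so plants of the groups handled differently at harvest may have contributed, and an effect of the genotype cannot be told apart from this, because the labels give no order or time of harvest within the groups. Within the groups, the per-array means of the touch genes and of the repressor and catabolism list varied together (r = 0.842 over deviations from the group means). Both were lowest on the brightest arrays of each group, Col-0 replicate 2 and bpm2,3,5 replicates 1 and 3. The r therefore does not tell a shared response from an effect of brightness.

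Among the clock genes, those that peak in the morning lay lower in the mutant relative to those that peak in the evening. The 6 tested morning genes had a mean log2 fold change of −1.24 (SE 0.289 over genes), all negative, and the 6 tested evening genes had 0.04 (SE 0.363 over genes), with 3 negative. Of the morning genes, CCA1, LHY and PRR9 were well above background on 2 of the 5 mutant arrays and RVE8 on 0. Their changes thus rest on signals near background, and the sign of RVE8 cannot be read. The evening genes were well above background on all 5 mutant arrays. The difference, evening minus morning, was 1.28 (p = 0.0303 by a 2-sided exact permutation test over genes, which are not independent replicates). A harvest of the groups at different times of day could give such a difference. It cannot be told apart from an effect of the genotype, because either could give the difference and the labels give no harvest time. The mean of the evening genes lay within its SE of 0, so a rise of the evening genes was not shown.

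The called genes did not cluster near the mutated loci. Linked variants that act on nearby genes would place many called genes beside BPM2, BPM3 and BPM5. Yet 1.79% of the 504 called genes with a place in the gene order lay among the 600 nearest tested genes, 100 on either side of each locus. Of those neighbours 5 rose and 4 fell, SPX1 near BPM5 among the latter. The share called was 1.50%, against 2.52% elsewhere (p = 0.965 by a 1-sided Fisher's exact test). This argues against effects of linked variants on neighbouring genes as the source of most calls. A linked variant that changes genes elsewhere in the genome would not be seen this way.

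Whether the groups differ by chance was tested with all 56 splits of the 8 arrays into 3 and 5. For genes higher in the mutant 2 splits gave as many as the real one, itself included, with a real count of 289 and a highest other count of 396, and for genes higher by 2-fold or more 2 splits with counts of 258 and 385. For genes lower in the mutant 1 split, the real one, gave as many (224, highest other 6), and likewise for genes lower by 2-fold or more (171, highest other 6). For the lower genes the share of splits was 0.0179, the smallest that 56 splits can give. This argues against chance but does not separate the genotype from the slide row. For the higher genes the share of splits is below 0.05, but another split gave more than the real one. The split that sets bpm2,3,5 replicates 2, 4 and 5 apart gave 4089 genes at an unadjusted limma p under 0.05, against 3857 for the real one. The split with 396 higher genes sets Col-0 replicate 2 and bpm2,3,5 replicates 1 and 3 apart, the brightest arrays, which points to a structure of the samples by brightness, and with brightness as a covariate 338 genes were higher and 260 lower. For the number of gene lists past the threshold 7 splits gave as many as the real 8 lists, the highest other being 13, so chance cannot be excluded for that number.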
